A study of Mus musculus with 8 samples.

How the data were processed

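Cortex was dissected from 4 WT and 4 TDP-43Q331K mice aged 4 months and flash-frozen, and RNA was extracted with TRIzol and a silica column, per the labels' protocols. Messenger RNA was captured with oligo(dT) beads, made into libraries with an Illumina stranded ligation kit and sequenced on a NovaSeq X, per the labels' protocols. The submitters' processing notes name STAR 2.7.6a, edgeR 4.4.2, R 4.3.1 and the build GRCm39, without saying what each was used for. The program that counted reads, its strand setting and its gene annotation are not given in the sources used here.

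The authors deposited raw counts per gene for the 8 libraries, per the file headers, with no scaling. The deposited table of normalised signal holds the same counts divided by a TMM-scaled library size, per the file headers and the constant ratio of value to count within each of its columns. The TMM factors implied by the deposited table ran from 0.987 to 1.015. Both tables hold the same 15693 genes, already filtered, and each library's column was matched to its sample through the library name in the labels, with 0 columns unmatched. Total counts per library ran from 45253021 to 58115164, so that 1 CPM stood for at least 45.3 counts.

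Gene symbols and biotypes were taken from GENCODE M21, which describes the build GRCm38, by gene identifier. A symbol was found for 15470 of the 15693 identifiers and not for 223. Because that build differs from the one the authors name, no coordinates are given, and the annotation served only for names, gene types, neighbour order, lengths and transcript sequences. Called genes and Tardbp were compared with all its transcripts by megablast, and 11 of 149 had a match to another gene of at least 90% identity over at least 50% of a transcript. Their counts are treated as uncertain, as are those of overlapping and antisense genes.

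TDP-43Q331K was compared with WT in R 4.3.3 with edgeR 4.0.16, using TMM factors, filterByExpr (which removed no gene), an intercept and genotype, and the two-sided quasi-likelihood F-test on 6 residual degrees of freedom. Adjusted p values are Benjamini-Hochberg over all 15693 genes, with a threshold of 0.05, and levels are CPM on TMM-scaled library sizes. The common biological coefficient of variation was 11.2%. For any pair of libraries of a group, chi-square per degree of freedom was between 14.6 and 28.0, so no pair of libraries was a copy. Batch was the same for all libraries.

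The genes to be named, the tests and 46 gene lists were chosen before the data were examined. The genes named were Tardbp, the 12 with the largest rise and the 12 with the largest fall among called genes with a mean log2 CPM of at least 0 and no overlap between groups, up to 4 members of each list with the smallest p, a few genes that can differ between substrains or sexes, and a small set of markers of neurons and glia. Genes named outside this rule are marked as chosen after their values were seen, and a few genes are not reported here. The lists cover excitability and synapses, cell types, adjoining tissues, TDP-43 and ALS, stress responses, and housekeeping functions. They were tested with limma 3.58.1 by camera at a preset inter-gene correlation of 0.01 where at least 5 members were measured, with an estimated correlation and with fry beside it. Benjamini-Hochberg adjustment ran over the 45 lists tested. Means of log2 CPM over a list were compared by two-sided exact permutation tests of 4 against 4 libraries, adjusted over 46 lists.

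The test was tried on simulated counts for the same comparison and 15693 genes, of which 200 were changed. It recovered 38.8% of 67 genes changed 1.25-fold, 64.2% of 67 changed 1.5-fold and 92.4% of 66 changed 2-fold. A simulated list of 18 further genes was lowered 1.15-fold. In all, 137 genes were called, of which 6 were unchanged and 1 belonged to that list. The lowered list was called, and 0 of 44 unchanged lists were. Each gene was simulated independently, so this does not test false calls of lists whose genes move together. The estimated correlation of the real lists reached 0.94, in striatal markers.

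The alternatives were RLE, upper quartile and library size scaling, no filter, a filter of CPM over 1 in 4 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2 of the deposited values plus 1, replicate number as a block, 1 surrogate variable from sva 3.50.0, Xist as a covariate, the sex chromosomes left out, a threshold of 0.10, and each library left out in turn. The replicate numbers come from the sample titles, and no label says that they mark a shared litter or day. Covariates made from the markers of 4 adjoining tissues were added after the data were seen. Figures and further tests used Python 3.11.15.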

Results

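Polyadenylated RNA was sequenced from the brain cortex of 8 mice, 4 of them wild type (WT) and 4 of the TDP-43Q331K line. TDP-43 is an RNA-binding protein encoded by Tardbp, and mice of this line carry a mutation linked to amyotrophic lateral sclerosis (ALS). All the mice were 4 months old and all the libraries belonged to batch 1, per the labels. Total counts were 50247051, 58115164, 52779021 and 45253021 in WT replicates 1 to 4, and 50446486, 54890055, 54126293 and 54248129 in TDP-43Q331K replicates 1 to 4. The 10 most counted genes held between 5.97% and 6.25% of the counts of a library, and mitochondrially encoded genes between 5.28% and 5.62%. The table held 15693 genes, each with at least 54 counts in 1 library. Counts were normalised by TMM and compared with edgeR's quasi-likelihood test, and levels are given as CPM, counts scaled to the TMM-adjusted library size.

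The libraries of a group were similar to each other but not uniform. Xist, which is transcribed in female cells, was at 984 and 876 CPM in WT replicates 2 and 3 and at 1015 and 905 CPM in TDP-43Q331K replicates 1 and 2. It was at most 1.37 CPM in the other 4 libraries, in which the Y-linked Ddx3y was between 64.9 and 71.5 CPM. Each group thus held 2 libraries of each sex, which the labels do not give. The first principal component of the log2 values held 30.1% of the variance and did not part the groups. Its scores ran from -23.23 to -5.45 in the libraries read as male and from -1.86 to 21.95 in those read as female. The second component held 24.3%, with WT scores from -4.11 to 25.5 and TDP-43Q331K scores no higher than -3.49. In WT the median gene's standard deviation was 7.3% of its mean.

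The comparison of the genotypes asked which transcripts of the whole cortex differ in the mutant mice, in a study of weakened cortical output to muscle and of motor cortex neurons that are less excitable. Tardbp (ENSMUSG00000041459) was measured first. It stood at 171, 198, 193 and 176 CPM in the WT libraries and at 162, 141, 167 and 149 CPM in the TDP-43Q331K libraries, so that the groups did not overlap. Its mean was 185 ± 12.8 CPM (SD, n = 4) in WT and 155 ± 11.7 CPM (SD, n = 4) in TDP-43Q331K, a log2 fold change of -0.25 (SE 0.07). This did not pass edgeR's test over all genes (adjusted p 0.106), whereas DESeq2 gave -0.26 with an adjusted p of 0.0117. Adjusted p ran from 0.0117 to 0.501 over the 16 alternatives that keep all the libraries. The labels do not say whether the line carries an added TDP-43 sequence or an edited mouse gene.

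Across the genome, 148 genes passed edgeR's test at an adjusted p under 0.05, 54 of them higher and 94 lower in TDP-43Q331K. They comprised 120 protein-coding genes, 27 non-coding genes or pseudogenes and 1 gene without an annotation. Most changes were small. The median absolute log2 fold change of the 148 genes was 0.42, 47 changed more than 1.5-fold, and 19 more than 2-fold, of which 12 rose and 7 fell. The groups did not overlap in any of the 148 genes. Over all genes this held for 1519, or 9.68%, where chance alone gives 2.86%. DESeq2 called 701 genes, among them the 148. With library size as the only scaling, 64 genes were higher and 73 lower. With the mean of olfactory and thalamic markers as a covariate, added after the data were seen, 12 were called (7 higher, 5 lower), and with replicate number as a block 14 (8 higher, 6 lower). Leaving out WT replicate 1, 2, 3 or 4 left 51, 73, 97 or 129 calls, and leaving out TDP-43Q331K replicate 1, 2, 3 or 4 left 81, 92, 71 or 97. None of the 148 changed sign in these 8 fits, and 44 were called in each of them.

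**Figure D1:**
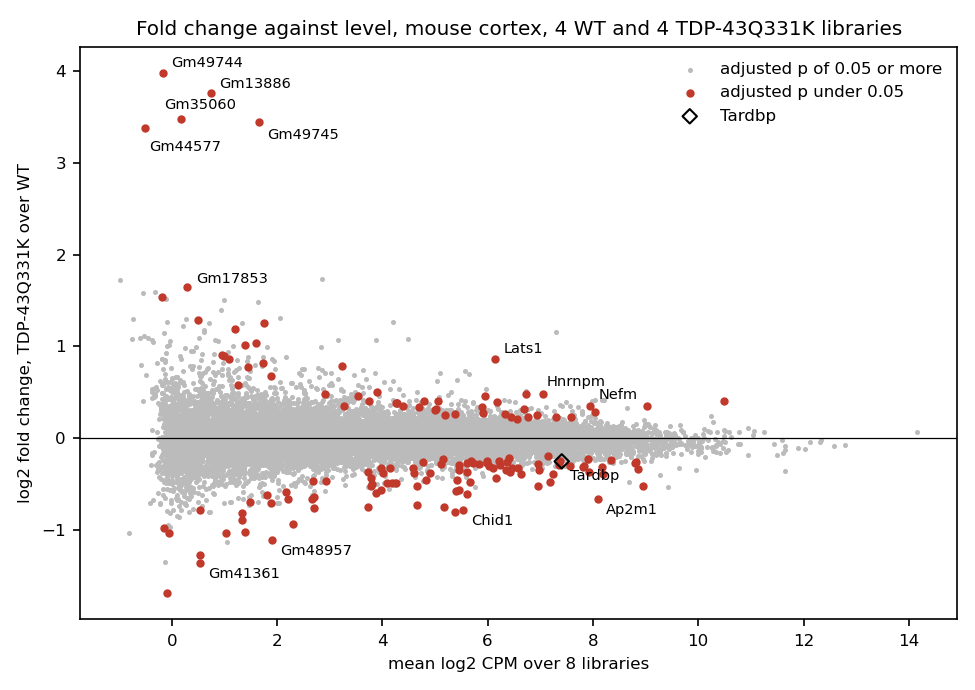
Log2 fold change of TDP-43Q331K over WT against mean log2 CPM over 8 libraries, for 15693 genes. Red points mark the 148 genes with an adjusted p under 0.05, and the diamond marks Tardbp, at -0.25.

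The steepest rises were in transcripts of low level and unknown function, among them copies of protein-coding genes. Gm13886, a processed pseudogene (ENSMUSG00000083856), went from 0.22 ± 0.0314 CPM (SD, n = 4) to 3.02 ± 0.27 CPM (SD, n = 4), a 13.6-fold rise with an edgeR adjusted p of 6.15e-06. Its sequence matched a Tardbp transcript at 94.2% identity over 1202 bases, so its count is uncertain. Gm35060 rose by 3.47 on the log2 scale, from 0.178 ± 0.123 to 1.98 ± 0.501 CPM (SD, n = 4). The intergenic RNA Gm49745 rose by 3.45, from 0.516 ± 0.1 to 5.68 ± 1.21 CPM (SD, n = 4). Adjacent to these lay Gm44577 and Gm49744, with log2 fold changes of 3.38 and 3.98, which were chosen after their values were seen. The processed pseudogenes Gm17853, Gm7061 and Gm14830 rose by 1.65, 1.26 and 1.29. Gm7061 was 91.6% identical to U2af2 and Gm14830 90.5% identical to Psmb1, and neither parent gene changed past the test. Trim43a rose by 1.18 but is 97.6% identical to its paralog Trim43b. The unclassified Gm44616 rose by 1.03 and the intergenic RNA 9230112J17Rik by 0.90. Adjusted p of these raised genes was at most 0.0327. Over the 8 fits that leave out 1 library, Gm14830 ranged from 1.16 to 1.39 and passed in 7, Gm44616 from 0.91 to 1.18 and passed in 2, and 9230112J17Rik from 0.78 to 0.97 and passed in 1.

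Among protein-coding genes of known product, Col2a1, which encodes the chain of type II collagen, rose 2.03-fold, from 1.69 ± 0.215 to 3.44 ± 0.341 CPM (SD, n = 4, edgeR adjusted p 0.00816). Sfn, which encodes the 14-3-3 sigma protein, rose from 1.48 ± 0.121 to 2.7 ± 0.144 CPM (SD, n = 4, edgeR adjusted p 0.0105). Noxred1, a predicted oxidoreductase gene, rose by 0.91 on the log2 scale (edgeR adjusted p 0.0409, passed in 1 of the 8 fits that leave out 1 library). At a higher level, Lats1, which encodes a kinase of the Hippo pathway, rose from 49.9 ± 2.71 to 90.7 ± 7.43 CPM (SD, n = 4), with a log2 fold change of 0.86 (SE 0.06, edgeR adjusted p 0.000295). It was chosen after its values were seen. It passed in each of the 8 fits that leave out 1 library, as did Col2a1 and Sfn.

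The largest falls were also mainly in non-coding transcripts. Gm41361, annotated as antisense, fell by 1.37 on the log2 scale, and whether counting used strand is not given in the sources used here, so its reads cannot be assigned with certainty. Gm47113 fell by 1.27, Gm48957 by 1.11, Gm32200 by 1.03, Gm30371 by 1.02 and Gm14827 by 0.94. Gm45716 fell by 0.89, BC065397 by 0.81, Gm19410 by 0.80 and Gm32679 by 0.79. Of these, Gm45716 and Gm19410 are annotated as protein-coding. Two-sided edgeR adjusted p lay between 0.00399 for Gm48957 and 0.0438 for Gm14827 and BC065397. Gm47113, Gm32200, Gm14827 and BC065397 passed in 3, 5, 2 and 1 of the 8 fits that leave out 1 library, and Gm32679 in 0 of them.

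A few protein-coding genes with known products and larger falls follow. Chid1, a gene of the chitinase-like family, fell from 58.6 ± 2.59 to 34.0 ± 5.24 CPM (SD, n = 4), a log2 fold change of -0.79 (SE 0.10, edgeR adjusted p 0.00711). Cep41, which encodes a centrosomal protein, fell from 8.13 ± 0.987 to 4.82 ± 0.161 CPM (SD, n = 4, edgeR adjusted p 0.00816). Ap2m1 encodes the mu subunit of the clathrin adaptor AP-2 and was chosen after its values were seen. It is a near neighbour of Gm49744 and Gm49745. It fell from 336 ± 14.9 to 211 ± 11.2 CPM (SD, n = 4), a log2 fold change of -0.67 (SE 0.05, edgeR adjusted p 0.000465). The pseudogene Gm13509, 99.7% identical to Ap2m1, fell by 0.72, and reads of this pair cannot be assigned with certainty. Each gene of this paragraph passed in the 8 fits that leave out 1 library.

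**Figure D2:**
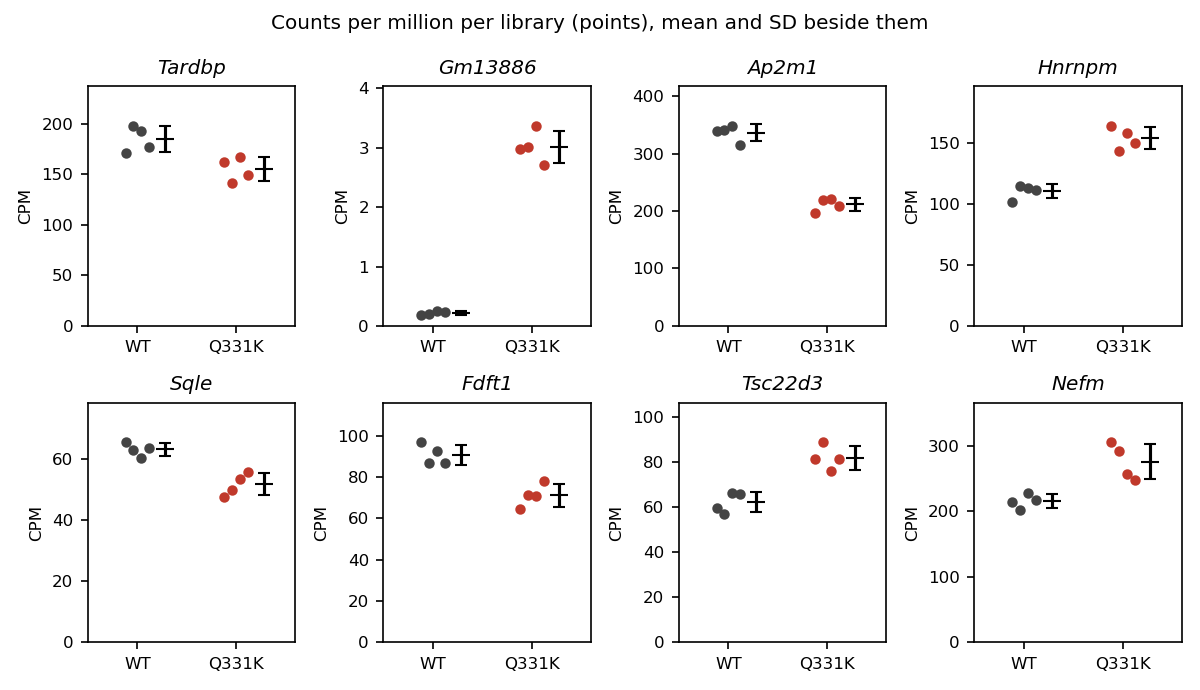
CPM of 8 genes in each library (points), with the mean and SD of 4 libraries beside them. Gm13886 was between 2.71 and 3.37 CPM in the TDP-43Q331K libraries and at most 0.248 CPM in WT, and the groups overlapped in none of the 8 genes.

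Of the 18 genes of cholesterol synthesis, 4 passed edgeR's all-gene test, all lower in TDP-43Q331K. Sterols are made in the brain itself, by neurons and glia, along a chain of enzymes that the transcription factor encoded by Srebf2 controls. Fdft1, squalene synthase, fell from 90.7 ± 4.89 to 71.2 ± 5.68 CPM (SD, n = 4), a log2 fold change of -0.35 (SE 0.06, edgeR adjusted p 0.0308). Sqle, the next enzyme, fell by 0.29 (edgeR adjusted p 0.0422), and Srebf2 by 0.22 (0.0416). The other 14 members did not pass, and 9 of the 18 were lower when adjusted over the list alone. Those 9 included Hmgcs1. The log2 fold change was negative in 17 of the 18, with a median of -0.191. The mean log2 CPM of the list was 5.80 ± 0.05 (SD, n = 4) in WT and 5.62 ± 0.09 (SD, n = 4) in TDP-43Q331K. The two-sided exact permutation p was 0.0286, the smallest that 4 against 4 libraries can give, and 0.493 adjusted over 46 lists. The competitive test camera, with a preset correlation, gave an adjusted p of 5.14e-10. With an estimated correlation, p was 0.0393 and adjusted p 0.771, and fry's directional adjusted p was 0.131, so that the list was called by neither, while fry's test for change in either direction gave 0.00135. Fdft1 passed in 2 of the 8 fits that leave out 1 library, and Srebf2 and Sqle in 1.

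Of the 45 lists tested, camera with the preset correlation called 13, of which 6 were higher and 7 lower. With a correlation estimated for each list, it called 0, with 2 at an unadjusted p under 0.05 and no adjusted p below 0.771. Fry's directional test also called 0, with 5 at an unadjusted p under 0.05, and its test for change in either direction called 12. Adjusted p values of lists are camera's at the preset correlation. Covariates made from the markers of adjoining tissues, added after the data were seen, are given where they ended the call of a list other than their own. Members past edgeR's all-gene test occurred in 5 lists, those of cholesterol synthesis, layer 6, splicing factors, axonal genes and glucocorticoid response. Members past the test adjusted over the list alone are counted where a list had any.

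**Figure D3:**
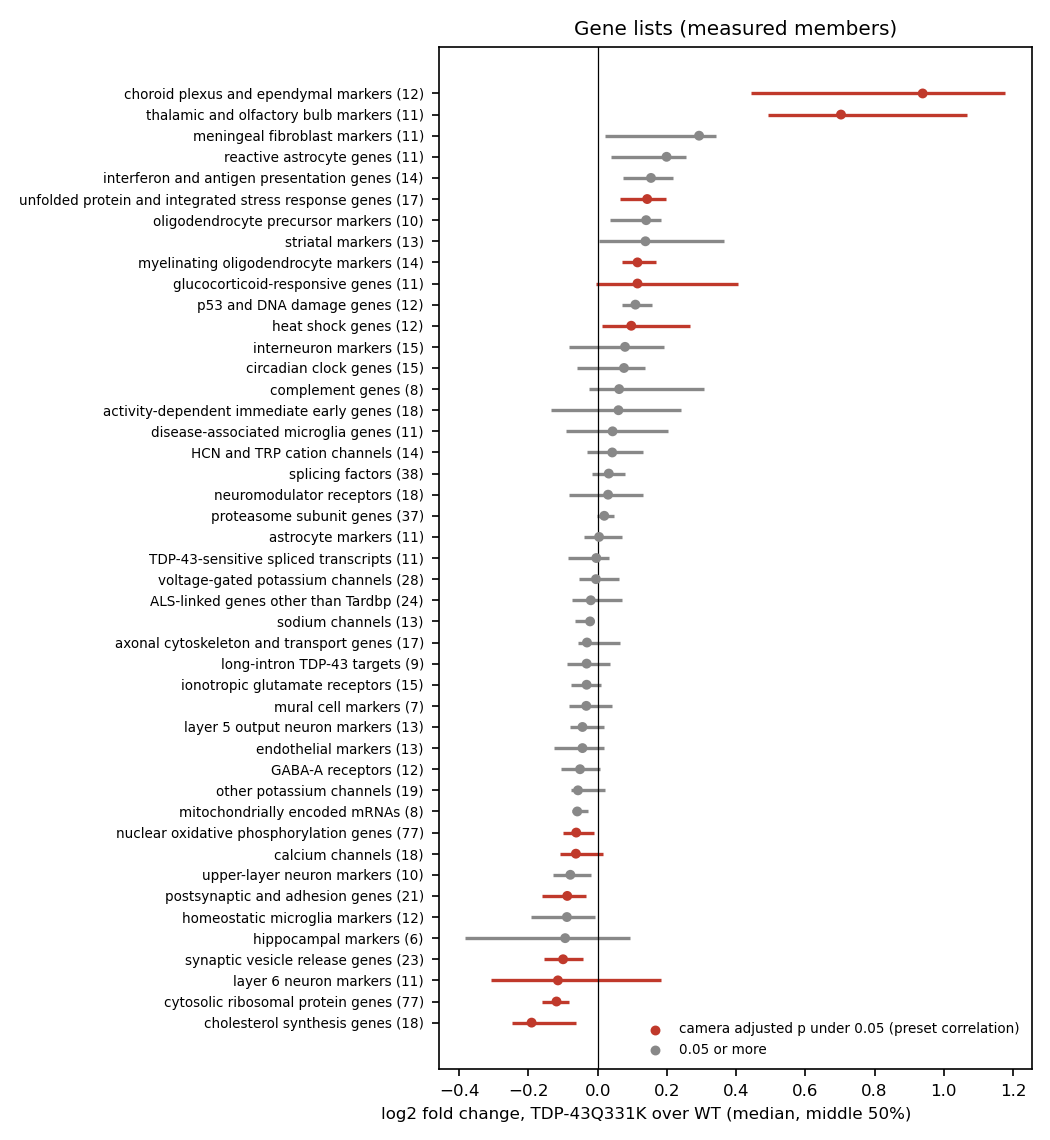
Median log2 fold change of TDP-43Q331K over WT (points) and the middle 50% of members (lines) for 45 gene lists, with the number of measured members in brackets. Red marks the 13 lists past an adjusted p of 0.05 with the preset correlation, from cholesterol synthesis genes at -0.191 to choroid plexus and ependymal markers at 0.939.

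Ion channels set the excitability of cortical neurons, and persistent inward currents run through sodium and calcium channels. None of the 13 sodium channel genes passed edgeR's all-gene test, 2 were lower at an unadjusted p under 0.05, DESeq2 called 1, and the list gave an adjusted p of 0.384. Its lowest p values were for Fgf13, at a log2 fold change of -0.18, and Scn3b, at -0.20. The 18 calcium channel genes were shifted down (adjusted p 0.0472, estimated-correlation p 0.221, median -0.063), with 11 negative, 0 past the all-gene test, 3 lower at an unadjusted p under 0.05, 2 called by DESeq2, and 2 lower when adjusted over the list alone. These were Cacna1e, which encodes the R-type channel, at 477 ± 42.9 CPM (SD, n = 4) against 342 ± 49.5 CPM (SD, n = 4) and a log2 fold change of -0.48 (SE 0.10, edgeR adjusted p 0.0639), and the auxiliary subunit Cacnb3 at -0.20 (0.0946). The calcium channel shift missed the threshold without WT replicate 2 (0.0891) or 4 (0.111) and without TDP-43Q331K replicate 2 (0.234) or 4 (0.201). It also missed it with library size as the only scaling (0.0517), with the filter of CPM over 1 (0.05), and with the olfactory and thalamic (0.221), choroid plexus (0.68) or striatal (0.0506) marker covariate. Voltage-gated potassium channels gave an adjusted p of 0.886, downward in the test with a median of -0.005 against a mean of 0.004, and the median turned to 0.009 with library size as the only scaling. Other potassium channels gave 0.396, with the glial Kcnj10 at 0.30 the only member past the test when adjusted over the list alone. HCN and TRP cation channels gave 0.36, with Hcn4 at 0.39, and neuromodulator receptors gave 0.88. Ionotropic glutamate receptors gave 0.399 and GABA-A receptors 0.316. Kcnv1, a voltage-gated potassium channel gene, and Cbarp, a calcium channel regulator gene, are in no list but passed edgeR's all-gene test. Both were chosen after their values were seen. Cbarp, at -0.31, passed in every fit that leaves out 1 library, and Kcnv1 did not.

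The 21 postsynaptic and adhesion genes had a median of -0.088 (adjusted p 0.00477, estimated-correlation p 0.142) and the 23 synaptic vesicle release genes a median of -0.1 (0.00284, estimated-correlation p 0.141). No member passed edgeR's all-gene test, 7 and 8 were lower at an unadjusted p under 0.05, and DESeq2 called 3 and 4. When adjusted over the list alone, 4 postsynaptic genes (Dlg3, Dlg4, Nrgn and Lrrtm2) and 3 vesicle genes (Stx1a, Sv2b and Rims1) were lower. Nrgn, which encodes the calmodulin-binding neurogranin, was at -0.40 (edgeR adjusted p 0.0678), Dlg4 at -0.16, Sv2b at -0.18 and Rims1 at -0.23. Both lists passed in each of the 8 fits that leave out 1 library, but neither did with the olfactory and thalamic marker covariate (0.505 and 0.0572), and the vesicle list did not with the choroid plexus covariate (0.0643). With the first covariate the medians were -0.041 and -0.063, and with the choroid plexus covariate that of the vesicle list was -0.091. Immediate early genes, which follow neuronal activity, gave an adjusted p of 0.848, with Fosl2 higher and Nr4a2 lower when adjusted over the list alone.

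Of the markers in 4 lists of cortical neurons, only Cplx3 passed edgeR's all-gene test. Cplx3, a complexin gene of deep-layer neurons, fell from 16.2 ± 1.94 to 11.3 ± 1.16 CPM (SD, n = 4), a log2 fold change of -0.52 (SE 0.10, edgeR adjusted p 0.0472), and passed in 1 of the 8 fits that leave out 1 library. It was 1 of 11 layer 6 markers to pass, and 4 were lower when adjusted over the list alone, with Ccn2 at -0.49 and Rprm at -0.39, while 4 of the 11 were positive. That list had an adjusted p of 0.0319 (estimated-correlation p 0.0571), which rose to 0.0746 without WT replicate 1 and 0.149 without TDP-43Q331K replicate 3, and to 0.0813 with the olfactory and thalamic marker covariate. The median of the list was -0.115, and -0.096 with that covariate. The two-sided exact permutation p of its mean was 0.171. Layer 5 output neuron markers gave 0.848, with Bcl6 and Nefh higher when adjusted over the list alone, and upper-layer markers gave 0.36. Interneuron markers gave 0.36, and Gad1 was at 0.19, Pvalb at -0.09 and Sst at 0.05.

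Glial and vascular lists showed no gene past edgeR's all-gene test. The 14 myelinating oligodendrocyte markers were all positive, with a median of 0.115 (adjusted p 0.0374, estimated-correlation p 0.458), 2 higher at an unadjusted p under 0.05 and 0 called by DESeq2. That shift missed the threshold without WT replicate 2 (0.193) or 4 (0.0503) and without TDP-43Q331K replicate 2 (0.265) or 4 (0.618). It also missed it with library size as the only scaling (0.0508, median 0.131) and with the striatal marker covariate (0.0546, median 0.111). With the olfactory and thalamic covariate (0.95) or the choroid plexus covariate (0.976), 8 or 7 of the 14 markers were positive and the median was 0.025 or 0.003. Oligodendrocyte precursor markers gave 0.0676. Homeostatic microglia markers gave 0.0513, with a median of -0.089 and P2ry12 lower, at -0.26, when adjusted over the list alone. Aif1 was at 4.89 CPM in both groups, and disease-associated microglia genes gave 0.724. Astrocyte markers gave 0.98, their median of 0.004 turning to -0.001 with RLE scaling, and reactive astrocyte genes gave 0.12, with Gfap at 0.24 (edgeR adjusted p 0.591). Endothelial markers gave 0.724, with Slc2a1 higher when adjusted over the list alone, and mural cell markers gave 0.848.

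Markers of tissues next to the cortex varied between libraries. Thalamic and olfactory bulb markers were higher in 11 of 11 members, with a median of 0.703 (adjusted p 0.00258, estimated-correlation p 0.0759). Their mean log2 CPM was 2.95 ± 0.85 (SD, n = 4) in WT and 3.89 ± 0.24 (SD, n = 4) in TDP-43Q331K (two-sided exact permutation p 0.0857). It was 2.28, 2.15, 3.75 and 3.61 in WT replicates 1 to 4 and ran from 3.56 to 4.09 over the 4 TDP-43Q331K libraries, so that the groups overlapped and WT replicates 1 and 2 were the lowest. Slc17a6, at 0.45, was higher when adjusted over the list alone, and Zic1 was at 1.08. Choroid plexus and ependymal markers were higher in 12 of 12 members, with a median of 0.939 and Aqp1 at 1.48 (adjusted p 0.00546, estimated-correlation p 0.293). Their mean log2 CPM ran from -0.21 to 2.47 over the 4 WT libraries and from 0.51 to 3.11 over the 4 TDP-43Q331K libraries, so that the groups overlapped, and the list missed the threshold without WT replicate 3 (0.0849) or TDP-43Q331K replicate 4 (0.171). No member of either list passed edgeR's all-gene test, 3 and 2 were higher at an unadjusted p under 0.05, and DESeq2 called 1 and 0. Meningeal fibroblast markers gave 0.352, and striatal and hippocampal markers gave 0.384 each. Of 6 blood cell markers, 2 were measured, too few for the test, with a median of 0.879.

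TDP-43 binds introns and controls splicing, which a count per gene measures only in part. Hnrnpm, which encodes a splicing factor, rose from 110 ± 5.83 to 154 ± 8.97 CPM (SD, n = 4), a log2 fold change of 0.48 (SE 0.06, edgeR adjusted p 0.00509), and passed in each of the 8 fits that leave out 1 library. It passed in 14 of the 16 alternatives that keep all the libraries, with an edgeR adjusted p of 0.00509 and a highest adjusted p of 0.0843 among them. A transcript of Hnrnpm was 100% identical to one of March2 over 1149 bases, so reads there cannot be assigned with certainty. March2 was at -0.04. Hnrnpm was the only 1 of 38 splicing factors to pass. Tra2a, at 0.32 (edgeR adjusted p 0.0508), joined it when adjusted over the list alone, and the list gave an adjusted p of 0.138. Transcripts spliced by TDP-43 gave 0.457, their median of -0.004 turning to 0.011 with library size as the only scaling, with Sort1 lower, at -0.17, when adjusted over the list alone. Long-intron targets gave 0.7, with Cadps higher, at 0.17, when adjusted over the list alone. ALS-linked genes other than Tardbp gave 0.517, and 0 of 24 passed edgeR's all-gene test, 3 higher and 4 lower had an unadjusted p under 0.05, and DESeq2 called 4. When adjusted over the list alone 4 were lower, namely Stmn2 at -0.20, Kif5a at -0.18, Grn at -0.22 and Tuba4a, and Unc13a was at -0.10. Nefm, a neurofilament gene, rose from 216 ± 10.7 to 276 ± 27.1 CPM (SD, n = 4, edgeR adjusted p 0.0480), and passed only without TDP-43Q331K replicate 4 among the 8 fits that leave out 1 library. It was 1 of 17 axonal cytoskeleton and transport genes to pass, before and after adjustment over the list alone, and that list gave 0.996, upward in the test against a median of -0.031. Nefl was at 0.04 and Mapt at -0.05. Transcripts of Nefm and Nefl were 100% identical over 1108 bases, so reads there cannot be assigned with certainty.

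Of the 7 lists of stress responses, camera with the preset correlation called 3, all upward. Tsc22d3, a target of the glucocorticoid receptor, rose from 62.4 ± 4.55 to 81.9 ± 5.28 CPM (SD, n = 4), a log2 fold change of 0.39 (SE 0.06, edgeR adjusted p 0.0171). It passed in 5 of the 8 fits that leave out 1 library. Of the 11 glucocorticoid-responsive genes 1 rose, 0 fell and 10 did not pass, and 5 were higher when adjusted over the list alone, among them Sgk1 at 0.52 and Arrdc2 at 0.50. The list gave an adjusted p of 0.00145, an estimated-correlation p of 0.0268 (adjusted 0.771, so not past the threshold) and a two-sided exact permutation p of 0.0286 (0.493 adjusted over 46 lists). Its median was 0.115, and 3 of the 11 members were negative. At the preset correlation it passed in each of the 8 fits and with each marker covariate. With the olfactory and thalamic covariate its adjusted p was 0.0241 and its median 0.106. Sgk1 was then at 0.25, Arrdc2 at 0.31 and Tsc22d3 at 0.28. Genes of the unfolded protein and integrated stress responses were positive in 16 of 17 members, with a median of 0.143 and Ddit4 at 0.34 (adjusted p 0.00546, estimated-correlation p 0.183). The list missed the threshold without TDP-43Q331K replicate 2 (0.129) or with the olfactory and thalamic marker covariate (0.0872). With that covariate the median was 0.1 and 15 of 17 members were positive. Heat shock genes gave 0.0293 (estimated-correlation p 0.308, median 0.097), with 3 of 12 higher when adjusted over the list alone and Hspa1b at 0.58. They missed the threshold without WT replicate 1 (0.0900) or TDP-43Q331K replicate 2 (0.405) and with that covariate (0.138, median 0.054). No member of these last lists passed edgeR's all-gene test, 3 and 4 were higher at an unadjusted p under 0.05, and DESeq2 called 1 and 2. The p53 and DNA damage genes gave 0.0676, interferon and antigen presentation genes 0.0858, complement genes 0.384 and circadian clock genes 0.479.

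Among genes of protein synthesis and respiration, none passed edgeR's all-gene test. The 77 cytosolic ribosomal protein genes were negative in 76 members, with a median of -0.119 (adjusted p 4.99e-11, estimated-correlation p 0.276), 19 lower at an unadjusted p under 0.05 and 5 called by DESeq2. Their mean log2 CPM ran from 6.53 to 6.81 over the 4 WT libraries and from 6.42 to 6.63 over the 4 TDP-43Q331K libraries, so that the groups overlapped (two-sided exact permutation p 0.2). Across coding genes Spearman's rho of log2 fold change with exonic length was 0.18, as far from 0 as in 16 of the 35 splits of the libraries, with a median of -0.044 in the shortest 10% and 0.04 in the longest 10%. Rps15a, at -0.34, and Rpl15, at -0.26, were lower when adjusted over the list alone, and the list passed in each of the 8 fits that leave out 1 library. The 77 nuclear oxidative phosphorylation genes had a median of -0.062 (adjusted p 0.00546, estimated-correlation p 0.604), with 4 lower at an unadjusted p under 0.05 and 0 called by DESeq2. Without WT replicate 3 that list turned upward (0.801), and without TDP-43Q331K replicate 3 or with the choroid plexus marker covariate it missed the threshold (0.224 and 0.236). Mitochondrially encoded mRNAs gave 0.36 and proteasome subunit genes 0.427.

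Genes that can differ between C57BL/6 substrains were read because the series text names C57BL/6N and the sample labels C57BL/6J for the WT mice. Neither gives the substrain of the TDP-43Q331K mice, so a difference of substrain between the groups is not excluded for any of the 148 calls. Wdfy1 was at 35.9, 35.4, 36.2 and 58.0 CPM in the WT libraries and at 21.9, 62.4, 22.0 and 41.3 CPM in the TDP-43Q331K libraries, so both groups held more than 1 level. Gabra2 was at -0.19 (edgeR adjusted p 0.348) and Ide at 0.11 (edgeR adjusted p 0.335). Nnt and Entpd4, also planned as checks, were not found among the measured gene symbols, and the reason was not tested.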

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

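The tests of Gm13886, of the neighbouring pairs and of the oligodendrocyte markers were chosen only after results were seen. So were those of the olfactory and thalamic and the choroid plexus covariates, and of other splits of the libraries. The transcript length test of the cholesterol genes was written before its own result but after the fold changes were seen.

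Single libraries stood apart from the other 3 of their group in 12 of 274 groups of values looked at, where chance gives about 13.7. WT replicate 4 had Wdfy1 at 58.0 CPM (others 35.4 to 36.2), Ide at 51.3 CPM (others 53.5 to 53.9), Nr4a2 at 48.2 CPM (others 68.7 to 71.7) and a mean log2 CPM of GABA-A receptors of 7.12 (others 7.02 to 7.03). WT replicate 3 had a mean log2 CPM of 3.02 for reactive astrocyte genes (others 3.22 to 3.25) and of 3.52 for complement genes (others 3.75 to 3.77). TDP-43Q331K replicate 2 had Kcnj10 at 246 CPM (others 202 to 204). TDP-43Q331K replicate 1 had Gfap at 84.6 CPM (others 167 to 173), a mean log2 CPM of 3.07 for reactive astrocyte genes (others 3.37 to 3.43) and one of 1.62 for meningeal fibroblast markers (others 2.55 to 2.64). TDP-43Q331K replicate 3 had a mean log2 CPM of 4.19 for striatal markers (others 5.33 to 5.39), and TDP-43Q331K replicate 4 had Dlg3 at 186 CPM (others 201 to 202).

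Gm13886, a pseudogene 94.2% identical to Tardbp, was higher in 4 of 4 TDP-43Q331K libraries. Reads of an unedited mouse Tardbp mRNA counted at Gm13886 would move with Tardbp, but the log2 fold change of Gm13886 exceeded that of Tardbp by 4.02. This does not cover reads of an edited mouse gene. In TDP-43Q331K replicates 1 to 4 Gm13886 stood at only 1.844%, 2.125%, 2.013% and 1.815% of the CPM of Tardbp. A raised neighbourhood is argued against by the 3 nearest measured genes on each side, whose median was 0.07 (from -0.05 to 0.29). A candidate explanation that stays open is RNA of an added TDP-43 sequence close enough to be counted there, since some lines of this name carry one under Prnp regulatory sequence. Prnp itself was at 0.14 (SE 0.06), above 0 but not past the all-gene test (edgeR adjusted p 0.270). A small addition is thus neither shown nor excluded, and the labels do not say how the line was made.

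Among the genes higher in TDP-43Q331K, 4 pairs were neighbours among the measured genes: Gm49744 with Gm49745, Gm35060 with Gm44577, 9230112J17Rik with Gm17853, and Gm7061 with Gm14830. Chance placement of independent genes is argued against, since 0 of 10000 random draws of as many genes held as many pairs (mean 0.19, at most 3). The lower genes held 1 pair, and 4267 of 10000 draws held at least as many. The draws matched only whether a gene was coding, not its level. Gm44577 is annotated as a bidirectional promoter RNA, so it may share a promoter with Gm35060, which was not tested. Reads of the parent genes U2af2 and Psmb1 are argued against for the pair of pseudogenes, the higher of the parents' log2 fold changes being 0.02. A wider raised neighbourhood is argued against by the 2 nearest measured genes on each side, with a median of -0.03 (from -0.67 to 0.15) where the pairs' members had 2.52. The lowest of these neighbours was Ap2m1, near Gm49744 and Gm49745, which was itself called lower (edgeR adjusted p 0.000465). Abcf3, which lies between Ap2m1 and that pair in the order of measured genes, was at -0.05 (edgeR adjusted p 0.593). A local change that lowers 1 gene and raises others is not excluded. Sequence that differs between the 2 groups of mice near these genes, and reads of overlapping genes counted at both members of a pair, stay open as untested, as does an effect of TDP-43.

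The 18 cholesterol synthesis genes had a median log2 fold change of -0.19 in TDP-43Q331K, with 4 of them called lower, and the list was not called with an estimated correlation or by fry's directional test. A lower share of myelinating oligodendrocytes is argued against, because the mean log2 CPM of their markers differed by 0.11 (SE 0.12) where the list differed by -0.17 (SE 0.05). More olfactory bulb tissue is argued against by the median with the olfactory and thalamic markers as a covariate, -0.21. With it 17 of 18 members were below 0, and the SD over members was 0.11 (0.12 without). For thalamic tissue that covariate cannot decide, because it hardly moved the thalamic markers. It took the olfactory bulb marker Eomes from 1.07 to -0.48, but the thalamic Prkcd only from 1.27 to 1.19 and Tcf7l2 from 0.76 to 0.75. The choroid plexus covariate took Prkcd to 0.14 and Tcf7l2 to 0.09, but Slc17a6 only from 0.45 to 0.30. With it the median of the cholesterol list was -0.254, and 1 of 18 members was positive. More thalamic tissue is thus argued against, as far as Prkcd and Tcf7l2 stand for it. A trend with transcript length is argued against by the median of 0.011 in coding genes of matched length (1000 draws from -0.07 to 0.11). Other differences in dissection, feeding or time of day, and shares of other cell types, were not tested. An effect of the genotype on sterol synthesis may remain, as a hypothesis, and the list's adjusted p of 0.771 with an estimated correlation sets its limit.

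Of the 35 splits of the 8 libraries into 4 and 4, only the real split, 1 of 35, gave as many as 148 called genes. The highest of the others gave 10, and that split parted the libraries by sex, as read from Xist. A share of 1 in 35 is the smallest that this test can give. Chance is thus argued against for that count but not excluded. The count does not part the mutation from a difference of substrain between the groups, which stays open as untested. For the gene lists, 20 of the 35 splits called at least 13, and the highest of the others called 26, so chance cannot be excluded for the number of lists called.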

How the results depend on the processing

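The marker covariates of adjoining tissues were chosen after the data were seen, and the other alternatives before. The count of 148 called genes stayed within 1.5 times under RLE, upper quartile and library size scaling, both filters, limma-voom, limma-trend, 1 surrogate variable, the Xist covariate, the sex chromosomes left out, and the choroid plexus and hippocampal covariates. DESeq2 called 701 (288 higher, 413 lower) and a threshold of 0.10 called 396 (171 higher, 225 lower); the cause of the DESeq2 count was not tested. The olfactory and thalamic covariate left 12 (7 higher, 5 lower). The log2 fold changes of the 148 genes kept their sign in 148 and a median 0.99 of their size, and their standard errors grew 1.37 times, so the calls ended through the wider error. The striatal covariate left 98 (35 higher), and the choroid plexus covariate gave 56 higher and 56 lower; the cause was not tested.

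With replicate number as a block, 14 genes were called (8 higher, 6 lower). Correlations of the deviations of same-numbered libraries were -0.412, 0.031, -0.079 and 0.033, so the numbers do not pair the samples. The block changed the count of lists to 14.

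Leaving out 1 library left 51 to 129 calls (18 to 53 higher, 33 to 76 lower), from fewer samples: 51, 73, 97 and 129 without WT replicates 1 to 4, and 81, 92, 71 and 97 without TDP-43Q331K replicates 1 to 4. Of the 148, 11 were called in every alternative. Tardbp ranged from -0.29 to -0.21 over these 8 fits and passed the threshold only with DESeq2, at -0.26 (adjusted p 0.0117, range over the alternatives 0.0117 to 0.501); the cause was not tested.

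The count of 13 lists fell to 6 with the olfactory and thalamic covariate and to 0 with an estimated correlation or fry's directional p, and was 11 to 17 with 1 library left out. The choroid plexus list turned over under its own covariate (adjusted p 0.681), by construction. The oxidative phosphorylation list ranged from 9.19e-07 to 0.801, turning upward without WT replicate 3.

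Of 89 genes followed across the alternatives, Tardbp among them, 36 were called. Of those 36, 26 lost their call with the block, 29 with the olfactory and thalamic covariate and at most 10 under any other alternative that keeps all the libraries. Besides Tardbp, DESeq2 added 33 calls. The filter of CPM over 1 left Gm44577 untested, and leaving out the sex chromosomes left 7 untested. Signs turned only in genes that passed in no setting. Gfap was at -0.08 and Pvalb at 0.01 with the choroid plexus covariate, and Gad1 at -0.16, Sst at -0.02, Psmb1 at -0.05 and Mapt at 0.00 with the olfactory and thalamic covariate. Aif1, at 0.00, was at -0.22 with that covariate, at -0.02 with upper quartile scaling, and within 0.02 of 0 otherwise. With 1 library left out, Wdfy1 ranged from -0.54 to 0.04, Pvalb from -0.22 to 0.09, Psmb1 from -0.02 to 0.07 and Aif1 from -0.06 to 0.07; the cause was not tested. At this depth and spread, 38.8% of the smallest simulated changes were recovered, so changes of that size were often missed.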

Other observations

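The test below was chosen after the fold changes were seen. Loss of TDP-43 function may lower genes with long introns. Across 13833 coding genes, which are not independent replicates, Spearman's rho of log2 fold change with gene span was 0.12, the opposite sign. Among the 35 splits of the libraries, 16 gave a rho as far from 0, and another split reached 0.29. Exonic length gave 0.18, with 16 of 35 splits as far from 0.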
